A study of Mus musculus with 12 samples.

How the data were processed

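Single-cell RNA of sorted synovial ILCs and fibroblasts of mice was read in 6 wells of 10x 3-prime chemistry, each with 3 hashtags. The library titles call the animals R5 mice. In experiment 1 the ILCs of healthy, STA and STA + Il23mc mice each filled a well of their own, with 3 hashed mice per condition; the fibroblasts of the 3 conditions shared 1 well, with 1 hashtag per condition. In experiment 2 healthy, mild STA and severe STA cells shared 1 well per cell type. The labels speak of cells pooled from 4 animals per well, while each well holds 3 hashtags, so the replicate is the hashtag: 1 mouse in the ILC wells of experiment 1, and an unknown number of animals elsewhere. By Xist and the Y-linked Ddx3y, 1 of 3 healthy, 2 of 3 STA and 1 of 3 Il23mc mice of experiment 1 were male; Ddx3y was at 0.17 CPM in the mild STA fibroblast hashtag and 28.5 to 59.0 CPM in the other 5.

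The deposited matrices hold raw UMI counts, made with Cell Ranger (6.1.2 per the file headers, 6.0.6 per the submitters' processing notes) on mm10. The authors also deposited a table of the 8042 cells they kept, with counts of UMIs, genes and hashtag UMIs per cell, the mitochondrial fraction (a share of the UMIs), a hashtag margin score, a hashtag call and a cell class; 8039 of these cells matched a barcode, in 5 of 6 wells. The tools and thresholds behind the fraction, the score and the classes are not stated in the deposited files. Gene positions came from GENCODE M21.

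For the wells and hashtags in the authors' table, their calls and classes were used. For the STA ILC well and the STA hashtags of the ILC well of experiment 2, hashtags were called with HTODemux (Seurat 5.3.0, quantile 0.99), which recovered 70.3 to 98.6% of the authors' calls where they exist, and cells were kept with at least 2000 UMIs (fibroblasts 1500), 700 genes and at most 10% mitochondrial UMIs. Classes were passed on from the annotated cells by 15 nearest neighbours in 30 components of 2000 variable genes (scanpy 1.11.5, scikit-learn 1.9.0; 10000 counts per cell). Tested on healthy cells of experiment 2 and across the healthy and Il23mc wells, none of them used for training, 90.1 to 99.4% of ILC2 cells and 19.4 to 71.5% of ILC3 cells got the authors' class. Of the cells the authors left out, 34.1 and 82.0% were recognised as such across wells and 53.6% within them.

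Cells without a hashtag call and, in annotated wells, cells outside the authors' table were left out of the sums, except where 1 rule for calls and classes was applied to all 3 wells. HTODemux called 141 to 1156 doublets per well, which were left out where its calls were used; doublets within 1 hashtag are not seen this way, and no other doublet call was made. UMIs were summed per mouse or hashtag and class: 795046 to 2030655 UMIs from 183 to 417 ILC2 cells per mouse in experiment 1, and 3103104 to 17064647 UMIs per fibroblast hashtag. Sums were compared with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filterByExpr; R 4.3.3), with an experiment term in fibroblasts, at a Benjamini-Hochberg adjusted p of 0.05. Tested on simulated data, this recovered 38% of 2-fold and 90% of 4-fold changes in ILC2 cells (9 false calls in 7175 genes) and 59% and 87% in fibroblasts (13 in 12000). The simulated counts were drawn from the kind of model that the test assumes, with no experiment or well effect. Recovery and false calls in the real data may therefore differ. Between mice of a group the counts of ILC2 cells varied 2.59 to 8.28 times as much as counting error gives, and those of fibroblast hashtags 6.88 to 50.9 times. Gene lists were tested with camera (limma 3.58.1, correlation 0.01). Class shares were compared with two-sided exact permutation tests. In the comparison of 1 fibroblast hashtag with 1, log2 CPM ratios carry 95% counting intervals. Lists and the largest ratios use genes with at least 50 counts in 1 hashtag, which single markers of other cells may not reach, and list medians are placed among 10000 random lists drawn from 20 bins of expression. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

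The comparisons, lists, first alternatives and genes to name were set before the data were examined. For each test the named genes are up to 10 higher and 10 lower with the largest change among those past the threshold, with a mean of at least 20 CPM in 1 group and no overlap of the groups. Sex-linked, mitochondrial, ribosomal protein, immunoglobulin and T cell receptor genes and predicted genes were left out of these. To these come up to 4 members of each list past the threshold, or 2 where none passed, and Il5, Il13, Areg, Gata3, Il17a, Il23r and Ifng in ILCs or Il6, Mmp3, Prg4, Cd200, Dkk3, Thy1 and Pdgfra in fibroblasts. A few genes that this rule picks are not reported here and were dropped with none in their place, while the list counts keep them. The comparison without a test used the same rule without the threshold. Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter, other cell sets, equal cell numbers, blocks and leaving out each replicate.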

Results

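Synovial innate lymphoid cells (ILCs) and synovial fibroblasts were compared between healthy mice, mice with serum transfer arthritis (STA) and mice with STA that also received an interleukin-23 minicircle (Il23mc). Levels are UMIs per 1e6 UMIs (CPM) of the cells of 1 mouse or 1 hashtag, given as mean and SD, and changes are log2 fold changes with their standard error (SE).

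In group 2 ILCs (ILC2) of STA mice, the genes of MHC class II antigen presentation stood far above their level in healthy mice. Cd74, the invariant chain that guides class II molecules, rose by 4.14 on the log2 scale (SE 0.29, adjusted p = 2.74e-06, edgeR; 3 mice per group), from 26.1 ± 11.1 to 445 ± 99.6 CPM. Of the type 2 and tissue-repair cytokines, Calca, which encodes the neuropeptide CGRP, rose by 1.65 (SE 0.339, adjusted p = 0.0163) and Areg, the EGF-family factor amphiregulin, by 0.94 (SE 0.2, adjusted p = 0.0201), from 848 ± 150 to 1560 ± 79.3 CPM. Areg was also among the leading genes of a cluster led by mast cell genes, with ILC2 as its main class. Whether the share of that cluster bears on the rise was not tested. Il13 and Il5, the classical ILC2 cytokines, did not pass: -0.09 (adjusted p = 0.904) and 0.71 (adjusted p = 0.198). In all, 212 of 7375 tested genes changed, 126 higher and 86 lower.

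Of the 5 measured MHC class II genes 4 rose and none fell, with a median of 4.14 (camera adjusted p = 4.76e-39; adjusted p = 0.00736 with an estimated correlation), and 5 rose when adjusted over the list alone. H2-Aa rose by 4.82 (SE 0.401), H2-Ab1 by 4.30 (SE 0.39) and H2-Eb1 by 3.90 (SE 0.385). Ctss, the protease that trims the invariant chain, rose by 2.53 (SE 0.255, adjusted p = 4.36e-05). In the 3 STA mice 5% of the ILC2 cells held 57.7 to 79.4% of the class II UMIs. Markers of other cells moved beside them: H2-Aa is also 1 of the 2 measured dendritic cell markers (list adjusted p = 1.55e-09; adjusted p = 0.00748 with an estimated correlation). The plasma cell gene Igkc rose by 2.66 (adjusted p = 0.0354), and 1 of the 2 measured B or plasma cell markers passed (list adjusted p = 0.0196; adjusted p = 0.141 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors on myeloid cells, rose by 3.49 (adjusted p = 0.0347), with 69.0 CPM in STA mouse 2 against 13.5 and 7.71 in the other STA mice. The classes of STA cells were passed on from other wells, so these sums may hold cells that the authors would have left out. With 1 rule for calls and classes in all 3 wells Cd74 rose by 4.58, Igkc by 5.77 and Fcer1g by 3.46.

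Of 20 activation and costimulation genes 5 rose, none fell and 15 did not pass (adjusted p = 6.60e-07; adjusted p = 0.00848 with an estimated correlation); adjusted over the list alone, 7 rose and 1 fell. Pdcd1, the inhibitory receptor PD-1, rose by 2.18 (SE 0.315, adjusted p = 0.00169), from 53.6 ± 31.5 to 231 ± 29.2 CPM. The costimulatory receptor Tnfrsf9 (4-1BB) rose by 1.46 and the activation marker Cd83 by 1.16. Tnfrsf4 (OX40), another costimulatory receptor, rose by 2.63 (SE 0.295, adjusted p = 0.000126). Of 9 type 2 and tissue-repair cytokines 3 rose and none fell (adjusted p = 0.000336; adjusted p = 0.141 with an estimated correlation), 5 adjusted over the list alone; the third was Il4, which drives type 2 responses, by 1.80 (adjusted p = 0.0185). The ILC2 marker list passed (adjusted p = 0.0229; adjusted p = 0.487 with an estimated correlation) with Areg alone of its 10 measured genes, or 2 adjusted over the list alone. None of 19 ILC2 identity genes passed, among them the transcription factors Gata3 (-0.06, adjusted p = 0.91), Rora (0.03) and Id2 (0.12).

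Of 13 lipid handling genes 3 rose and 1 fell, 4 and 4 adjusted over the list alone. Dgat2 and Dgat1, which make triglycerides, rose by 2.52 (SE 0.208, adjusted p = 9.45e-06) and 0.94 (adjusted p = 0.0358), and the lipid droplet coat Plin2 rose by 1.70. Of 15 trafficking and residency genes 2 rose and 2 fell, 3 and 3 adjusted over the list alone: the chemokine receptor Cxcr6 (0.68) and the integrin Itga4 (0.94) rose, S1pr1, which draws lymphocytes out of tissue, fell by 1.73 (adjusted p = 0.00643) and Rgs2 fell by 0.51. Of 7 type 1 and NK genes 2 rose, the chemokine Ccl5 (3.46) and the kinase Txk (1.98), and the receptor Klrk1 (NKG2D) fell by 1.86, with 2 and 3 adjusted over the list alone (median -0.11, mean 0.28, test downward). Of 19 immediate early and dissociation genes 2 fell, Klf6 by 0.98 and Zfp36 by 0.89, with 1 higher and 3 lower adjusted over the list alone. Single members of other lists rose: Ldha of 20 glycolysis genes (0.49), H2afz of 17 cell cycle genes (0.66) and Uqcrb of 18 oxidative phosphorylation genes (0.63; 5 adjusted over the list alone; list adjusted p = 0.000171; adjusted p = 0.437 with an estimated correlation). The interferon list passed upward (adjusted p = 0.0107; adjusted p = 0.141 with an estimated correlation) and the cycling list downward (adjusted p = 0.0131; adjusted p = 0.487 with an estimated correlation), each with no single gene past the threshold in edgeR, over all genes or over the list alone. Irf1 was at 0.11, Isg15 at 0.33, Top2a at -0.71 and Mki67 at -1.37.

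The largest rises outside the MHC genes were Plac8 and AA467197 (4.05, SE 0.479, edgeR adjusted p = 0.000202). Plac8 had 0 UMIs in the healthy mice of experiment 1. It was at least 62.1-fold higher in STA against a floor of 3 counts over the group (27.3-fold without STA mouse 2). In experiment 2, with 1 well, Plac8 was at 2.37 CPM in the healthy hashtag and 25.3 and 7.77 CPM in the mild and severe STA hashtags. The largest falls were the tubulin-binding genes Tppp (-3.26, SE 0.407, adjusted p = 0.000356) and Tppp3 (-2.65), then Dpysl3 (-2.42), the receptor chain Il6ra (-2.29), Dmxl2 (-2.13), Wee1, a kinase that holds cells before mitosis (-2.05), the tetraspanin Cd9 (-1.999) and Crip2 (-1.90). Il17a, the signature cytokine of group 3 ILCs (ILC3), stood at 1.73 (edgeR adjusted p = 0.597). Without cells holding a Cd3d or Cd3e UMI it stood at -0.58, not called either. Il23r and Ifng had 5 against 2 and 18 against 1 UMIs and were not tested. Tmem176a and Tmem176b of the ILC3 list did not pass (0.09 and 0.01), nor did markers of other cells: the T cell genes Trbc1 (0.16) and Trbc2 (0.54), the mast cell genes Kit (-0.15) and Hdc (1.77), Thy1 (-0.33), Ly6c1 (2.20), Mbp (-0.24), Runx2 (-0.07), Pecam1 (0.17), Hba-a1 (-0.79), Itga6 (-0.58) and Hbegf (-0.44). The 14 lists that did not pass had adjusted p from 0.0734 to 0.776.

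The 2 groups did not overlap in 209 of the 212 changed genes, and in 22.9% of all tested genes, where chance gives 10%. In experiment 2, where healthy and STA cells shared 1 well, 183 of the 212 genes moved the same way in both STA hashtags (86.3%), 16 in 1 and 13 in neither. Of the 7163 genes not called 45.4% moved the same way in both, and the 2 share 1 healthy hashtag, so they are not independent. This counts direction alone: in the mild and severe hashtags Areg was at 0.25 and 0.02, Il13 at 0.03 and -0.73 and H2-Ab1 at 2.02 and 0.31 (counting interval -0.38 to 1.00 in the severe). In experiment 2 the healthy ILC2 cells were classed by the authors and the STA cells by transfer, as in experiment 1. Cells that the authors would have left out may thus sit in the STA sums of both experiments. In experiment 1 each condition was its own well, so well and condition cannot be told apart there. The count was 138, 74 and 58 without healthy mouse 1, 2 and 3, 88 and 73 without STA mouse 1 and 2, and 28 in the sum over all lymphoid cells. Of the 39 named genes that passed, 16 kept their call whichever mouse was left out, among them Cd74, H2-Aa, H2-Ab1, H2-Eb1, Ctss, Pdcd1, Tnfrsf4, Tnfrsf9, Dgat2, Txk, Tppp, Dmxl2, Wee1, Crip2, Klrk1 and AA467197. The other 23, whose adjusted p ran from 0.000433 to 0.27 over the leave-outs, lost it. Their highest values were, without healthy mouse 3, Areg 0.0995, Calca 0.112, Cd83 0.0684, Cd9 0.0754, Cxcr6 0.188, Klf6 0.0697, Tppp3 0.0697 and Zfp36 0.201. Without healthy mouse 2 they were Il4 0.119, Ccl5 0.0621, Plac8 0.0924, Plin2 0.0656, S1pr1 0.0606 and Dpysl3 0.144. Without STA mouse 2 they were Fcer1g 0.27, Igkc 0.176, Il6ra 0.115, Itga4 0.261, Ldha 0.254, Rgs2 0.259 and Uqcrb 0.154. Without STA mouse 1 they were Dgat1 0.151 and H2afz 0.122.

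**Figure D1:**
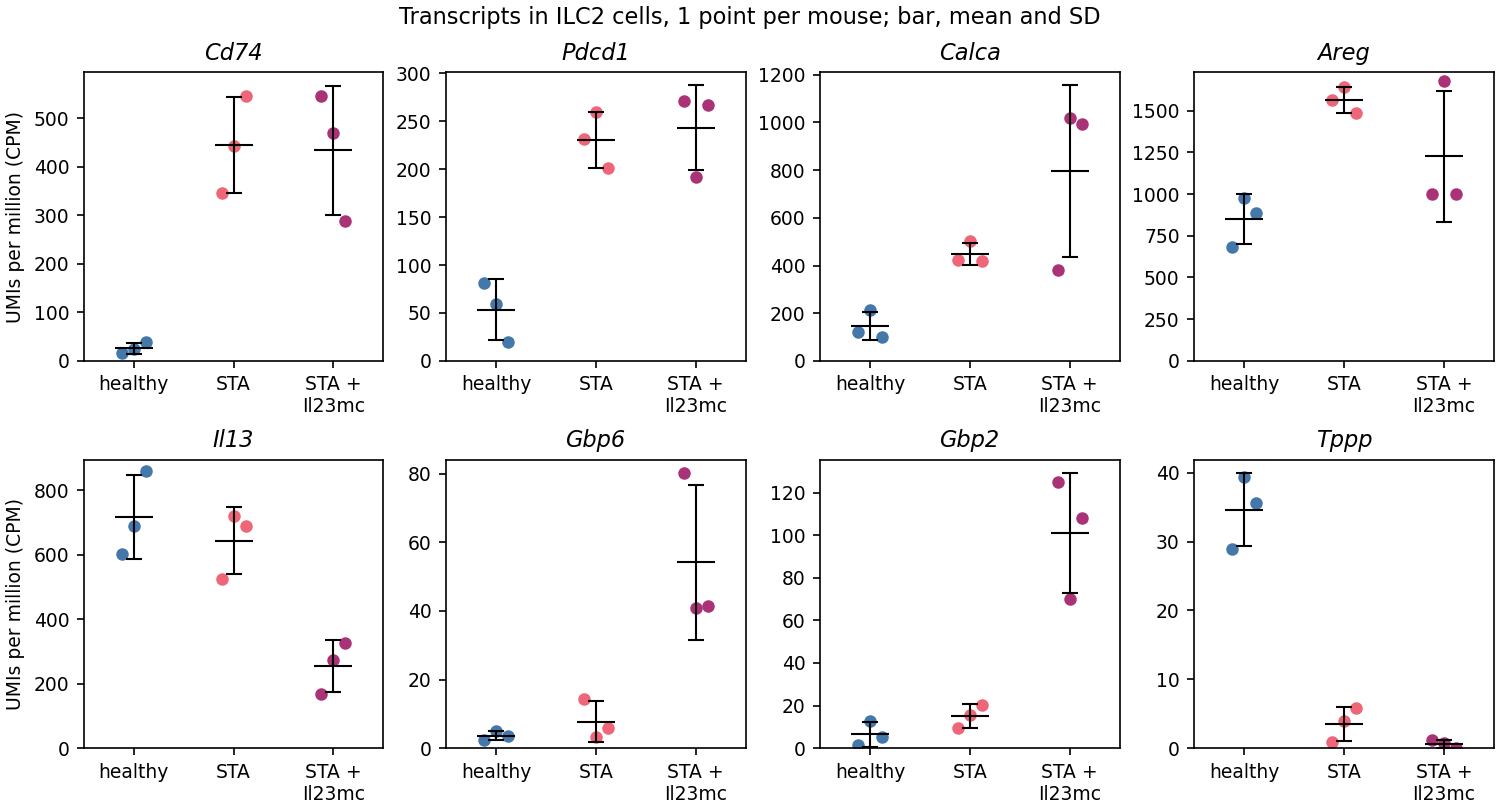
Level of 8 genes in ILC2 cells (CPM on the y axis, 1 panel per gene) in the healthy, STA and STA + Il23mc mice of experiment 1. Each point is 1 mouse and the bars are mean and SD of 3 mice; for Cd74 the healthy mice lie between 16.4 and 38.2 CPM and the STA mice between 346 and 545 CPM.

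In STA mice that received the Il23mc, ILC2 cells held more interferon response transcripts and less Il13 than in STA alone. The guanylate-binding protein gene Gbp2 rose by 2.77 (SE 0.359, adjusted p = 0.000641, edgeR; 3 mice per group), from 15.1 ± 5.50 to 101 ± 28.1 CPM. Il13 fell by 1.28 (SE 0.228, adjusted p = 0.00755), from 644 ± 104 to 256 ± 80.9 CPM. Il22, an ILC3 cytokine, had 1432 UMIs against 1 (log2 ratio 10.56, counting interval 8.07 to 15.86; edgeR adjusted p = 0.0034), with 1270, 170 and 48.6 CPM in the 3 Il23mc mice. In all, 130 of 7375 genes changed, 86 higher and 44 lower.

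Of 15 measured interferon response genes 9 rose, none fell and 6 did not pass, with a median of 1.36 (adjusted p = 4.58e-28; adjusted p = 0.00132 with an estimated correlation); adjusted over the list alone, 12 rose and 1 fell. Gbp7 rose by 1.39 and the transcription factor Irf1 by 1.00 (adjusted p = 0.0233). Other interferon-inducible GTPase genes were among the largest rises: Gbp6 (2.81, SE 0.386), Iigp1, with 116 UMIs against 1 (log2 ratio 6.93, counting interval 4.42 to 12.25), and the near-identical pair Tgtp1, with 99 UMIs against 3 (log2 ratio 5.12, counting interval 3.53 to 7.42), and Tgtp2 (3.43), between which reads are not reliably told apart. Of 20 activation and costimulation genes 2 rose and 3 fell, 5 and 3 adjusted over the list alone (list adjusted p = 0.678): Cd274, the PD-1 ligand, rose by 1.31 (adjusted p = 0.0104) and the inhibitory receptor Ctla4 by 3.81 (adjusted p = 0.031), while Tnfrsf4 fell by 1.18 and Cd83 by 0.92. The MHC class II genes did not change further, with Cd74 at 0.00 (adjusted p = 0.999) and H2-Aa at -0.64, and Zbtb46, the other measured dendritic cell marker, was at -0.65.

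Of 15 type 3 and IL-17 genes 3 rose and none fell (adjusted p = 0.0035; adjusted p = 0.437 with an estimated correlation), and 5 adjusted over the list alone. Il17a rose by 4.22 (SE 0.875, adjusted p = 0.0219), with 634, 231 and 23.3 CPM in the 3 Il23mc mice, and the membrane protein gene Tmem176b rose by 0.81. The ILC3 markers passed with Il22, Il17a and Tmem176b of 7 genes, 5 adjusted over the list alone (adjusted p = 1.31e-07; adjusted p = 0.281 with an estimated correlation). T cell transcripts moved beside them: in Il23mc mouse 1, 2 and 3 the ILC2 cells held 479, 99.8 and 11.1 CPM of the T cell receptor chain gene Cd3d. Without cells holding a Cd3d or Cd3e UMI, an alternative chosen after the data were seen, Il22 was at 45.4, 25.7 and 46.9 CPM, Il17a at 15.1, 27.3 and 22.9 CPM, and the change in Il17a was 2.93 and in Il13 -1.10, both still called. Leaving out these cells does not take away free RNA, and ILC3 cells of the same 3 mice held Il17a at 1332, 2671 and 152 CPM and Il22 at 1768, 3268 and 1222 CPM, so the source of what is left stays open. In mice 1 and 2 nearly all these UMIs lay in annotated ILC3 cells that held Cd3d or Cd3e. They were 3616 of 3632 and 3585 of 3591 for Il17a, and 4814 of 4821 and 4389 of 4394 for Il22. In mouse 3 they were 11 of 18 for Il17a and 0 of 145 for Il22. Without the ILC2 cells holding Cd3d or Cd3e, Ctla4 stood at 0.72, Ccr7 at -1.27, Cd83 at -0.77, Hopx at -1.41, Rgs18 at -1.25 and Itgb7 at 0.48, none of them called. Thy1 (-0.76) and Runx2 (-1.12) were then called. Gzmb, the cytotoxic protease granzyme B and 1 of 7 type 1 and NK genes to rise, changed by 2.89 (adjusted p = 0.0496) and by 2.37 without those cells.

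Of 9 type 2 and tissue-repair cytokines Il13 alone fell (adjusted p = 0.0425; adjusted p = 0.424 with an estimated correlation), and 2 fell and 1 rose adjusted over the list alone. Il5 stood at -0.11, Areg at -0.29 and Gata3 at 0.08, none past the threshold. Both measured B or plasma cell markers fell (adjusted p = 2.98e-08; adjusted p = 0.0131 with an estimated correlation): Ighm fell by 2.44 and Igkc from 114 UMIs to 1 (log2 ratio -6.76, counting interval -12.08 to -4.25). Of these groups the STA cells alone were classed by transfer, so the STA sums may hold cells that the authors would have left out. The haemoglobin gene Hba-a1 fell by 2.85 and the T cell receptor gene Trbc1 by 0.82. Of 15 trafficking and residency genes Rgs1 (0.73) and the integrin Itgb7 (0.63) rose, and Ccr7, a receptor that guides cells to lymph nodes, fell by 1.66, with 4 and 2 adjusted over the list alone. The heat shock gene Hsp90aa1 (1.07) rose and the respiratory chain gene Ndufa4 fell by 0.74, each alone in its list. Pde5a (4.45), a phosphodiesterase, and Cryba4 (4.34) also rose; without the cells holding Cd3d or Cd3e they stood at 1.89, 2.41 and 6.55 CPM and at 11.3, 4.82 and 9.82 CPM in the 3 Il23mc mice and no longer passed the filter on low counts. Stab2 (-2.93), the transcription factor Sox4 (-2.25), the lysosomal enzyme gene Gusb (-1.55), Hopx (-1.47) and Rgs18 (-1.46) fell.

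Eno1b (2.95) and Bc1 (2.86) rose, and Gstp1 (-2.36), the glycolysis gene Eno1 (-1.93) and Polr2l (-1.67) fell; Eno1 and Eno1b are near-identical, so reads are not reliably told apart. In fibroblasts all 5 differ by well whatever the condition. Eno1b was at 2.63 to 3.01 CPM in the 3 hashtags of experiment 1 and 30.6 to 68.1 CPM in those of experiment 2, Bc1 at 0.876 to 4.28 against 122 to 243 CPM, Gstp1 at 107 to 123 against 2.26 to 3.10 CPM, Eno1 at 105 to 273 against 27.1 to 42.3 CPM, and Polr2l at 54.0 to 90.1 against 18.4 to 22.8 CPM. No change was called in Thy1 (0.02), Dgat1 (0.72), Dgat2 (-0.26), Hbegf (1.64, adjusted p = 0.0807), Itga6 (0.26), Ly6c1 (1.71), Kit (-0.15), Hdc (-0.89), Mbp (-0.63), Runx2 (-0.32), Pecam1 (0.44), Rora (0.06), Id2 (0.34), Top2a (0.59), Mki67 (0.09), H2afz (-0.05) or Hmgb2 (0.31). Il23r and Ifng were not tested. The 18 lists that did not pass had adjusted p from 0.0742 to 0.906; median and mean differ in sign for the trafficking (0.13 and -0.01), lipid (0.01 and -0.07) and ILC2 marker lists (0.02 and -0.05), and the cell cycle test pointed down at a median of 0.09.

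The Il23mc and STA mice did not overlap in 125 of the 130 genes, and in 16.2% of all tested genes, where chance gives 10%. The count was 62 without Il23mc mouse 2, 69 and 65 without STA mouse 1 and 2. Of the 37 named genes that passed, 14 kept their call whichever mouse was left out, among them Gbp2, Gbp6, Iigp1, Tgtp1, Tgtp2, Il22, Il13, Ighm, Cryba4, Eno1, Eno1b, Bc1, Gstp1 and Polr2l. The other 23, at 0.000232 to 0.215 over the leave-outs, lost it. Their highest adjusted p were, without STA mouse 2, Ccr7 0.215, Ctla4 0.148, Il17a 0.114, Gzmb 0.206, Cd274 0.0785, Cd83 0.186, Gusb 0.0606, Ndufa4 0.0947, Pde5a 0.0563, Rgs1 0.113, Sox4 0.0730 and Trbc1 0.169. Without Il23mc mouse 2 they were Irf1 0.132, Tnfrsf4 0.18, Igkc 0.0593, Hba-a1 0.13, Hopx 0.123 and Stab2 0.0842. Without STA mouse 1 they were Gbp7 0.0643, Rgs18 0.186 and Tmem176b 0.0757, and without STA mouse 3, Hsp90aa1 0.159 and Itgb7 0.135.

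Against healthy mice, ILC2 cells of the Il23mc mice carried both sets of genes. Cd74 rose by 4.14 (SE 0.29, adjusted p = 1.94e-06, edgeR; 3 mice per group) and Gbp2 by 3.73 (SE 0.389, adjusted p = 2.73e-05), from 6.46 ± 5.86 to 101 ± 28.1 CPM. Calca rose by 2.55 (SE 0.345, adjusted p = 0.000273), while Il13 fell by 1.36 (SE 0.228, adjusted p = 0.00155), from 717 ± 132 to 256 ± 80.9 CPM. In all, 553 of 7375 genes changed, 343 higher and 210 lower, and 507 genes changed in the test of any difference between the 3 conditions.

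All 5 measured MHC class II genes rose, with a median of 3.84 (adjusted p = 3.20e-23; adjusted p = 0.0161 with an estimated correlation), among them H2-Aa by 4.18, H2-Ab1 by 3.84 and H2-Eb1 by 3.09. H2-Aa was again 1 of 2 dendritic cell markers (list adjusted p = 0.000325; adjusted p = 0.0411 with an estimated correlation). Of 15 interferon response genes 11 rose, as many as adjusted over the list alone, with a median of 1.86 (adjusted p = 1.46e-26; adjusted p = 0.000597 with an estimated correlation), including Gbp2, Gbp7 (1.86) and Irf1 (1.11). Iigp1 (116 UMIs against 1, log2 ratio 7.11, counting interval 4.60 to 12.42) and Ifitm1, an interferon-induced membrane protein (111 against 1, 7.04, 4.53 to 12.36), rose beside them. Without the cells holding Cd3d or Cd3e, Iigp1 was still called, while Ifitm1, at 5.67, 4.82 and 4.37 CPM in the 3 Il23mc mice, did not pass the filter on low counts. Of 20 activation and costimulation genes 8 rose and 1 fell (adjusted p = 1.31e-05; adjusted p = 0.0161 with an estimated correlation), 11 and 2 adjusted over the list alone: Pdcd1 rose by 2.29, the IL-2 receptor chain Il2ra by 0.74 and the costimulator Icos by 0.63. Ctla4 had 1229 UMIs against 2 (log2 ratio 9.51, counting interval 7.65 to 12.56). Of 13 lipid handling genes 3 rose, Dgat2 (2.26), Plin2 (2.18) and Dgat1 (1.67), and 3 fell, 4 and 4 adjusted over the list alone, among them Hmgcs1, an enzyme of cholesterol synthesis, which fell by 1.39. Of 19 ILC2 identity genes 5 rose, or 7 with 1 lower adjusted over the list alone, among them Icos, Il2ra, the IL-7 receptor Il7r (0.58) and Id2 (0.46). Of 9 type 2 and tissue-repair cytokines 1 rose and 1 fell, 3 and 1 adjusted over the list alone; Il5 (0.60, adjusted p = 0.212) and Areg (0.65, adjusted p = 0.0641) did not pass, and both were called without the cells holding Cd3d or Cd3e (0.81 and 0.85).

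Of 15 type 3 and IL-17 genes 6 rose (adjusted p = 0.000361; adjusted p = 0.303 with an estimated correlation), 8 adjusted over the list alone, and of 7 ILC3 markers 5 rose (adjusted p = 1.10e-05; adjusted p = 0.234 with an estimated correlation). Il22 had 0 UMIs in healthy mice and was at least 567-fold higher, against a floor of 3 counts over the group (at least 159-fold without Il23mc mouse 1, and at least 47.7-fold without the cells holding Cd3d or Cd3e). Il17a rose by 5.95 (SE 1.03, adjusted p = 0.00193), Tmem176b by 0.82 and Tmem176a by 0.67, and Il17f, the partner of Il17a, had 224 UMIs against 3 (log2 ratio 6.47, counting interval 4.90 to 8.76). T cell markers rose with them, 4 of 7, and 1 fell, 6 and 1 adjusted over the list alone (adjusted p = 0.00559; adjusted p = 0.437 with an estimated correlation): Cd3d by 6.57, Trdc by 4.52 and Cd3g by 2.74, while Trbc1 fell by 0.66. Without the cells holding Cd3d or Cd3e, Il17a rose by 2.35, Ctla4 by 5.86 (45.4, 27.3 and 31.6 CPM in the 3 Il23mc mice) and Gzmb by 1.53. Tmem176a then stood at 0.16 (adjusted p = 0.648) and Cd3g at -0.07, neither called, and Il17f at 3.78, 3.21 and 12.004 CPM. Of 7 type 1 and NK genes Ccl5 (3.73) and Gzmb (3.64) were among 3 that rose, and Nkg7 (-1.77), a cytotoxic granule gene, and Klrk1 (-1.76) fell. Of 2 measured sublining fibroblast markers Ly6c1, also a marker of activated lymphocytes, rose by 3.91. Of the B or plasma cell markers Ighm fell by 1.87 (list adjusted p = 0.0222; adjusted p = 0.17 with an estimated correlation), Hba-a1 fell by 3.64, and Mbp, a myelin gene, fell by 0.86.

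Plac8 had 0 UMIs in the healthy mice of experiment 1 (at least 62.5-fold higher against the same floor, and at least 36.1-fold without the cells holding Cd3d or Cd3e). AA467197 rose by 6.17 (SE 0.457) and Gramd3 had 64 UMIs against 1 (log2 ratio 6.25, counting interval 3.72 to 11.57). The tubulin-binding genes Tppp, with 2 UMIs against 143 (log2 ratio -5.91, counting interval -8.97 to -4.03), and Tppp3, with 3 against 105 (-4.88, -7.18 to -3.30), fell, as did Stab2 (-3.51), Dpysl3 (-2.93), Dmxl2 (-2.42), Crip2 (-2.19), Itsn1 (-2.15) and Emp1 (-2.02). Of 15 trafficking and residency genes 4 rose, Rgs1 (0.95), the chemokine receptors Cxcr4 (0.79) and Cxcr6 (0.65) and the cAMP-responsive factor Crem (0.75), and 1 fell, the same adjusted over the list alone. Of 19 immediate early and dissociation genes Egr1 (1.86) and Hsp90aa1 (1.26) rose and Klf6 fell by 0.87, or 4 and 3 adjusted over the list alone (median -0.17, mean 0.12). Ldha (0.47) rose and Eno1 (-1.49) fell among 20 glycolysis genes, Uqcrb rose (0.62) among 18 oxidative phosphorylation genes and H2afz (0.61) among 17 cell cycle genes. The near-identical Eno1b moved the other way, with 37.4 to 55.7 CPM in Il23mc and 11.3 to 19.7 CPM in healthy mice. Reads of Eno1 and Eno1b are not reliably told apart, and both differed by well in fibroblasts. Il23r, with 59 UMIs against 2 (log2 ratio 5.13, counting interval 3.21 to 8.21), and Ifng, with 18 against 1 (4.42, 1.75 to 9.80), did not pass the filter on low counts and were not tested. Without the cells holding Cd3d or Cd3e, Il23r was at 0, 1.61 and 2.18 CPM and Ifng at 1.89, 0 and 1.09 CPM in the 3 Il23mc mice. Not called were Gata3 (0.03), Top2a (-0.12), Mki67 (-1.28), Hbegf (1.20), Itga6 (-0.32), Kit (-0.30), Hdc (0.87), Pecam1 (0.61) and Runx2 (-0.39), which was called without those cells (-1.19). The 15 lists that did not pass had adjusted p from 0.0506 to 0.948.

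The Il23mc and healthy mice did not overlap in 522 of the 553 genes, and in 24.4% of all tested genes, where chance gives 10%. The count was 327 and 333 without healthy mouse 2 and 3, and that for any condition 291 and 294. Of the 60 named genes that passed, 40 kept their call whichever mouse was left out, among them Cd74, Gbp2, Calca, Il13, Il22, Il17a, Pdcd1 and Dgat2. The other 20, at 0.000121 to 0.199 over the leave-outs, lost it. Their highest adjusted p were, without healthy mouse 2, Cd3g 0.0843, Egr1 0.0674, Gramd3 0.0558, Gzmb 0.0605, Ighm 0.0919, Ly6c1 0.0858, Mbp 0.0731 and Trdc 0.0585. Without healthy mouse 3 they were Crem 0.16, Cxcr6 0.119, Id2 0.169, Il2ra 0.0615, Il7r 0.17, Ldha 0.126 and Uqcrb 0.0647. Without healthy mouse 1 they were Cxcr4 0.106, Tmem176a 0.173 and Trbc1 0.199, and without Il23mc mouse 2, H2afz 0.0906 and Nkg7 0.105.

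ILC2 cells made up 54.2 ± 20.03% of the classed ILCs of healthy mice, 60.6 ± 8.46% of STA mice and 53.2 ± 24.3% of Il23mc mice, and ILC3 cells 39.0 ± 21.1%, 32.8 ± 10.1% and 39.2 ± 30.5%. No class share differed beyond the spread between mice (two-sided exact permutation tests, 3 mice per group, all p at least 0.4 and all adjusted p = 1; the smallest p that 3 against 3 can give is 0.1). In STA mice the classes were passed on from other wells, which gave 19.4 to 71.5% of ILC3 cells the authors' class. In Il23mc mice 410 of 462, 180 of 221 and 7 of 28 ILC3 cells held Cd3d or Cd3e UMIs.

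In STA fibroblasts Cxcl5, Tnfsf11, Mmp3 and Col1a1 rose, while Dcn and Cd34 fell. Cxcl5, a chemokine that attracts neutrophils, rose by 4.67 (SE 0.19, adjusted p = 0.000428, edgeR with an experiment term; 3 STA and 2 healthy hashtags), from 29.4 ± 1.86 to 709 ± 220 CPM. Tnfsf11, the osteoclast factor RANKL, rose by 3.89 (SE 0.364, adjusted p = 0.0022), the matrix protease Mmp3 by 2.08 (SE 0.2, adjusted p = 0.00242), from 295 ± 102 to 1133 ± 280 CPM, and Col1a1, the main chain of type I collagen, by 1.67 (SE 0.143, adjusted p = 0.00168). Dcn, the proteoglycan decorin, fell by 1.12 (SE 0.0954, adjusted p = 0.00167) and Cd34, a marker of sublining fibroblasts, by 1.54 (SE 0.181, adjusted p = 0.00369). In all, 2481 of 12200 tested genes changed, 1276 higher and 1205 lower. Of 32 lists tested 16 passed camera with the preset correlation and 0 with the estimated one (camera of limma; 2 lists at an unadjusted p under 0.05, smallest adjusted p = 0.373).

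Of 29 collagens and matrix proteins 15 rose and 2 fell (adjusted p = 9.01e-12; adjusted p = 0.373 with an estimated correlation), 17 and 2 adjusted over the list alone; Col3a1 rose by 1.19 and Col1a2 by 1.15. Of 15 myofibroblast and TGF-beta-induced genes 10 rose and none fell, with a median of 1.47 (adjusted p = 1.22e-10; adjusted p = 0.373 with an estimated correlation), 10 and 2 adjusted over the list alone. They include Cthrc1, a secreted marker of activated fibroblasts (3.62, SE 0.16, adjusted p = 0.000434), Tpm1, a tropomyosin (1.47), and the matricellular protein Ccn1 (0.62). All 6 measured tenocyte markers rose (adjusted p = 2.90e-10; adjusted p = 0.373 with an estimated correlation), among them the tendon factor Scx (3.09), Thbs4 (2.45), Fmod (1.39) and Tnmd (1.29). Within 1 class Fmod stood at -0.095 (Mmp3+), -0.19 (Il6+) and -0.27 (Pi16+) and Tnmd at -0.14 (Mmp3+), while the Mmp3+ share was 6.64% in healthy and 53.1% in STA hashtags. Of 18 matrix-degrading enzymes 7 rose and 3 fell (adjusted p = 0.0241; adjusted p = 0.373 with an estimated correlation), 10 and 4 adjusted over the list alone: besides Mmp3, Ctsk (0.60) and Mmp2 (0.56) rose and Ctsl fell by 0.37. In the lining class alone Ctsk stood at -0.50 and in the Mmp3+ class alone Ctsl at 0.56.

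Of 28 inflammatory mediators 11 rose and 5 fell (adjusted p = 0.0192; adjusted p = 0.373 with an estimated correlation), 11 and 8 adjusted over the list alone. The prostaglandin synthase Ptgs2 rose by 0.63, while the chemokine Cxcl1 fell by 0.59 and the chemokine Ccl2 fell by 1.06. Il6 did not pass (-0.48, adjusted p = 0.0587; 315, 821 and 685 CPM in STA against 542 and 919 in healthy). Ccl20 (4.42, SE 0.671), Slpi, a secreted inhibitor of neutrophil proteases (3.73), Ccl9 (3.36) and Ccl5 (2.17), also an ILC1 or NK marker, rose as well. Of 10 complement genes Cfb rose (0.61) and 3 fell, among them C4b by 1.11 and Serping1 by 0.70. Within 1 class C4b stood at 0.41 (Mmp3+) and 0.57 (Pi16+), Serping1 at 0.51 (Mmp3+) and Cfb at -1.10 (lining). Of 10 genes of IL-4 and IL-13 reception and response 2 rose, Il13ra1 (0.85) and the alarmin Il33 (0.45), and Ccl11, an eosinophil chemokine, fell by 1.44, with 2 and 2 adjusted over the list alone. In the Mmp3+ and the Il6+ class alone Ccl11 stood higher in STA, at 1.13 and 0.72, neither called. The IL-33 receptor gene Il1rl1 rose by 2.70 (SE 0.17, adjusted p = 0.000625), the 1 of 3 measured ILC2 markers to pass (list adjusted p = 0.00834; adjusted p = 0.503 with an estimated correlation; median -0.21, mean 0.57, test upward). Of 15 receptors for arthritis cytokines 2 fell, Ifngr1 by 0.53 and Pdgfra by 0.45. Of 22 interferon genes Bst2 (0.92) was among 3 that rose, and 2 fell, Irf1 by 1.26 and Gbp2 by 0.98, with 3 and 4 adjusted over the list alone.

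Of 14 universal fibroblast genes 12 fell and none rose, with a median of -1.13 (adjusted p = 8.13e-12; adjusted p = 0.373 with an estimated correlation), the same numbers adjusted over the list alone: Ly6c1 fell by 1.296, the hyaluronan synthase Has1 by 0.92 and Ly6a (Sca-1) by 0.72. Of 10 sublining markers 4 fell, among them Clec3b by 1.71, and Sfrp1 rose by 2.05, with 3 higher and 5 lower adjusted over the list alone (list adjusted p = 0.0284; adjusted p = 0.579 with an estimated correlation). Of 12 lining genes 3 fell, the protease inhibitor Timp3 by 1.38, Cd55 by 1.59 and Clu by 0.63, and the adhesion molecule Vcam1 rose by 0.61, with 1 and 4 adjusted over the list alone. Prg4, the joint lubricant lubricin, stood at -0.27 (adjusted p = 0.813), with 23657 and 3386 CPM in the healthy hashtags of experiments 1 and 2. Of 14 Wnt antagonists and ligands 3 rose, among them Sfrp2 (2.40), and 5 fell, among them Sfrp4 by 1.15 and Dkk2 by 0.74, with 5 and 7 adjusted over the list alone. Of 9 CD200/DKK3 fibroblast genes 5 rose and 2 fell, the same adjusted over the list alone (adjusted p = 3.90e-07; adjusted p = 0.373 with an estimated correlation), a list recalled from the study and so not independent of these samples. Postn (1.95) and Dkk3 (1.28, adjusted p = 0.00945) rose, Cd200 fell by 1.02 (adjusted p = 0.0314), and Thy1 was at -0.51 (adjusted p = 0.0952).

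Of 23 cell cycle genes 13 rose and none fell (adjusted p = 3.45e-08; adjusted p = 0.519 with an estimated correlation), 18 and 1 adjusted over the list alone, among them Birc5 (2.54), Mki67 (1.34), Stmn1 (1.24) and Hmgb2 (0.80). Of 9 cycling markers 7 rose, 8 adjusted over the list alone (adjusted p = 1.58e-06; adjusted p = 0.503 with an estimated correlation), with Ccnb2 (2.13) and Cenpf (1.86). In the Mmp3+ class alone Mki67 stood at -0.69, Stmn1 at -0.67, Hmgb2 at -0.16, Cenpf at -0.082 and Ccnb2 at -0.012, none of them called. Of 21 glycolysis and hypoxia genes 10 rose and 2 fell, 12 and 2 adjusted over the list alone (adjusted p = 0.00165; adjusted p = 0.373 with an estimated correlation), with Pkm (1.01), Gapdh (0.81), Tpi1 (0.81) and Ldha (0.60). Of 18 oxidative phosphorylation genes 8 rose, 12 adjusted over the list alone (adjusted p = 0.00111; adjusted p = 0.664 with an estimated correlation), with Atp5e (0.60), Cox6c (0.57), Cox7c (0.49) and Ndufa4 (0.47). Of 19 immediate early and dissociation genes 1 rose and 5 fell, 1 and 8 adjusted over the list alone (adjusted p = 0.0241; adjusted p = 0.503 with an estimated correlation), among them Atf3 by 0.76, Junb by 0.67, Hspa1b by 0.59 and Btg2 by 0.48.

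Markers of other cells also moved. Of 5 skeletal muscle markers 4 fell (adjusted p = 0.0192; adjusted p = 0.373 with an estimated correlation), Ckm by 1.38, Mylpf by 1.09, Tnnt3 by 0.85 and Acta1 by 0.84. Of 10 chondrocyte or osteoblast markers 4 rose, among them the cartilage genes Acan (2.58) and Sox9 (1.28) and the bone factor Runx2 (0.97), and 2 fell, among them osteocalcin, Bglap, by 2.63. Acta2, smooth muscle actin, rose by 1.61 and Abcc9, a pericyte gene, fell by 0.75. Both measured ILC3 markers, Tmem176a (1.63) and Tmem176b (1.37), rose (adjusted p = 4.77e-06; adjusted p = 0.373 with an estimated correlation), the Schwann cell marker Ncam1 rose by 1.52, and the dendritic cell marker Zbtb46 fell by 1.32. Igkc (1.36, adjusted p = 0.0829), Ighm (-0.45), Trdc (-0.11), Kit (-2.39, adjusted p = 0.0528), Cd14 (0.78), Lyz2 (-0.27), S100a8 (0.45), S100a9 (0.21), Eng (0.17), Pecam1 (-0.50), Hba-a2 (-1.45), Hbb-bs (0.17) and Hbegf (0.17) did not pass. Other large rises were Ddah1 (3.62), the chitinase-like Chil1 (3.33), Nt5dc2 (3.28) and the adhesion molecule Chl1 (3.18). The largest falls were S100g (-4.82, SE 0.305, adjusted p = 0.000625), Pou2f2 (-3.80), Scg3 (-3.62), Fmo2 (-3.38), Aldh3a1 (-3.04), Stmn4 (-2.86), Myoc (-2.85), Galnt15 (-2.79), the leptin receptor Lepr (-2.75) and Ltbp4, which binds latent TGF-beta (-2.74). The 16 lists that did not pass had adjusted p from 0.108 to 0.9.

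STA and healthy hashtags did not overlap in 2249 of the 2481 genes, and in 43% of all tested genes, where chance gives 20%. The count was 841 without the experiment 1 healthy hashtag, 911 without the experiment 1 STA hashtag, 583 without the experiment term, 6 in the lining class alone, 512 in the Mmp3+, 199 in the Il6+ and 68 in the Pi16+ class alone. Of the 98 named genes that passed, 40 turned direction in at least 1 class alone, in 55 values of which none was called. The healthy hashtags of experiments 1 and 2 held 10 and 29 Mmp3+ cells and 49 and 6 lining cells, so signs there rest on few healthy cells. The leave-outs are not separate checks. With the experiment term, those without the healthy or the STA hashtag of experiment 1 both rest on experiment 2 alone. That without the healthy hashtag of experiment 2 rests on 1 hashtag against 1 in experiment 1. Of the 98, 57 kept their call whichever hashtag was left out, among them Cxcl5, Tnfsf11, Mmp3, Col1a1, Cthrc1, Cd34, Dcn and Il1rl1. The other 41, at 0.000309 to 0.34 over the leave-outs, lost it. Their highest adjusted p were, without the experiment 2 healthy hashtag, Il33 0.34, Ckm 0.313, Runx2 0.116, Mylpf 0.0951, Cfb 0.0708, Hspa1b 0.0657, Btg2 0.0615, Ctsk 0.0577 and Vcam1 0.0560. Without the experiment 1 STA hashtag they were Ccl5 0.241, Ctsl 0.163, Junb 0.0713, Cxcl1 0.0593 and Has1 0.0593. Without the experiment 1 healthy hashtag they were Ccl20 0.101, Cd200 0.156, Dkk3 0.0709, Pdgfra 0.101, Mmp2 0.194, Birc5 0.0536, Mki67 0.203, Hmgb2 0.209, Stmn1 0.0703, Cenpf 0.163, Acta2 0.148, Acta1 0.121, Tnnt3 0.231, Abcc9 0.178, Zbtb46 0.105, Bglap 0.0564, C4b 0.0720, Serping1 0.0985, Ccl11 0.0716, Ccn1 0.0569, Clu 0.255, Cox6c 0.134, Cox7c 0.165, Ndufa4 0.145, Dkk2 0.159, Ifngr1 0.0862 and Ly6a 0.0587.

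No share of a fibroblast class passed the test. Cells of the class named for Mmp3 made up 6.64 ± 5.92% of the 2 healthy and 53.1 ± 14.8% of the 3 STA hashtags, and cells of the class named for Pi16, a marker of universal fibroblasts, 48.6 ± 2.28% and 17.1 ± 7.52%. The Cd200+ class held 6.60 ± 1.41% and 2.91 ± 0.964%, the Il6+ class 31.0 ± 4.69% and 22.1 ± 7.52%, and the lining class 7.12 ± 6.91% and 4.79 ± 0.859%. In two-sided exact permutation tests the first 3 classes gave p = 0.1, the smallest that 2 against 3 hashtags can give (adjusted p = 0.167), the Il6+ class 0.3 and the lining class 0.8.

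**Figure D2:**
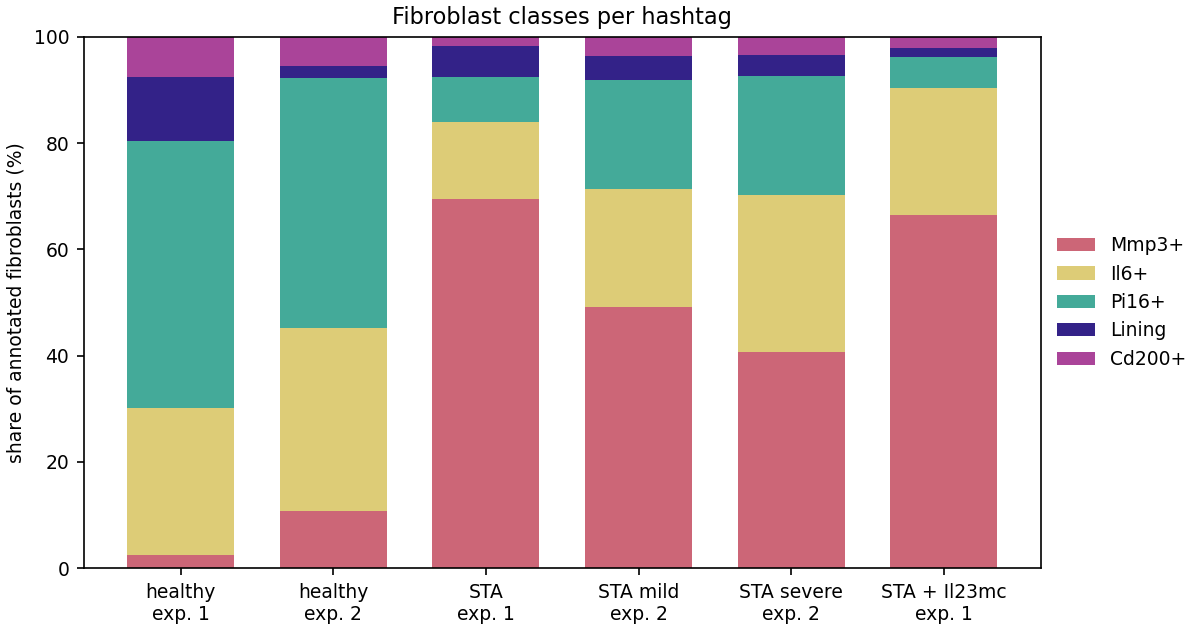
Share of fibroblasts in each class (percent on the y axis) for the 6 hashtags of experiments 1 and 2, with 1 stacked bar per hashtag. The Mmp3+ class holds 2.45 and 10.8% of the healthy hashtags and 40.6 to 69.5% of the STA hashtags.

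With the Il23mc, fibroblasts of experiment 1 held more inflammatory mediator and complement transcripts than those of STA alone, and fewer lining, cell cycle and myofibroblast ones. This sets 1 hashtag against 1, so there is no replicate error and no test, and intervals hold counting error alone. TMM factors would raise every log2 ratio by 0.22, so how many genes lie above or below 0 depends on the scaling, while percentiles do not. The random lists were drawn gene by gene, so percentiles take no account of genes that move together, and extreme ones are easier to reach. Saa3, an acute-phase protein gene, stood at 4830 against 1070 CPM (log2 ratio 2.18, interval 2.15 to 2.20), Lcn2, the antibacterial lipocalin, at 1480 against 111 CPM (3.74, interval 3.67 to 3.81) and Mmp3 at 3732 against 1356 CPM (1.46, interval 1.44 to 1.48). In the lining class alone the Mmp3 ratio was 0.26.

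Of 28 inflammatory mediators 24 had intervals above 0 and 2 below, with a median of 0.77, above all 10000 random lists of matched expression. They include the B cell chemokine Cxcl13 (4.44, interval 4.23 to 4.65), Cxcl12 (1.27), Ccl7 (0.85), Cxcl1 (0.58) and Ccl5 (2.04). All 9 complement genes lay above 0, with a median of 1.02 at percentile 100: C3 (1.45), Cfb (1.19), Serping1 (1.15) and C4b (1.02). Of 9 genes of IL-4 and IL-13 reception and response 5 lay above 0 and none below (median 0.40, percentile 99.99), with Il33 (0.92), Il4ra (0.54), Socs3 (0.40) and Il13ra1 (-0.05). Of 15 receptors for arthritis cytokines 8 lay above and 3 below (median 0.27, percentile 100), with Il1r1 (0.73), Pdgfra (0.30), Il6st (0.21) and Il11ra1 (-0.06). Of 23 interferon genes 10 lay above and 9 below (median 0.05, percentile 99.99). Among interferon-induced genes Iigp1 stood at 3.27, Irf1 at 0.17, Bst2 at 0.05 and Ifi27l2a at -1.15, and Rsad2 was among the largest falls. Of the matrix-degrading enzymes 8 lay above and 8 below (median 0.09, percentile 99.4), or 11 and 2 with TMM factors, with Ctsl (0.78), Mmp2 (-0.03) and Mmp13 (-0.54). Il6 stood at 656 against 315 CPM (1.06, interval 1.01 to 1.10), but the STA hashtags of experiment 2 held 821 and 685 CPM.

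None of 23 cell cycle genes had an interval above 0 and 22 lay below, with a median of -0.81, under all random lists: Stmn1 (-1.06), Tuba1b (-0.71), H2afz (-0.43) and Hmgb2 (-0.34). All 9 cycling markers lay below (median -0.90), among them Birc5 (-0.96), Top2a (-0.87), Ccnb2 (-0.77) and Mki67 (-0.71). Of 15 myofibroblast and TGF-beta-induced genes 11 lay below and 2 above (median -0.72, under all random lists), with Tgfbi (-1.11), Cthrc1 (-0.94) and Tpm1 (-0.72). Of 12 lining genes 9 lay below and 3 above (median -0.67), with Timp3 (-0.96), Hbegf (-0.67), Vcam1 (0.15) and Prg4 (0.11), and the lining markers Htra4 (-1.02) and Col22a1 (-1.25) lay below too. Of 6 tenocyte markers 5 lay below (median -0.97), with Kera (-2.17), Tnmd (-1.23), Fmod (-0.72) and Thbs4 (-0.21). Of 29 collagens and matrix proteins 19 lay below and 9 above (median -0.29, percentile 0.715), or 16 below and 12 above with TMM factors (median -0.07), with Col1a2 (-0.22), Col1a1 (-0.16), Col3a1 (0.14) and Sparc (0.03). Of 18 oxidative phosphorylation genes none lay above and 18 below (median -0.33, percentile 1.02), or 1 above and 11 below with TMM factors (median -0.10), with Cox7c (-0.32), Cox6c (-0.31), Atp5e (-0.22) and Cox4i1 (-0.13). Of 9 CD200/DKK3 genes, the list recalled from the study and not independent of these samples, 3 lay above and 6 below (median -0.25, percentile 26.0), with Aspn (-0.93), Dkk3 (-0.50), Postn (-0.04) and Sfrp2 (1.13).

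The universal (median -0.12, percentile 83.0; 5 above, 7 below) and Wnt lists (median -0.12, percentile 87.3; 4 above, 5 below) lay inside the random lists, with Pi16 (0.55), Ly6a (0.35), Ly6c1 (0.23), Has1 (0.02), Sfrp1 (0.18) and Sfrp4 (0.17). Among sublining markers Cxcl14 was at 0.97, Mfap5 at -0.16 and Thy1 at -0.73, and Cd200 was at 0.40. Against the mean of all 3 STA hashtags Prg4 was at -0.01, Cd200 at -0.43, Pdgfra at -0.03 and Il6 at 0.11. Of 20 glycolysis and hypoxia genes 9 lay above 0 and 5 below (median 0.02, percentile 99.7), or 14 and 1 with TMM factors, with Gapdh (0.06), Ldha (0.09), Pkm (0.04) and Eno1 (-0.02). Of 19 immediate early and dissociation genes 12 lay above and 3 below (median 0.11, percentile 93.1), or 19 and 0 with TMM factors, with Hspa8 (0.11), Fos (0.02), Hsp90aa1 (0.22) and Egr1 (0.15). The other largest ratios were Mt3, a metallothionein (4.56, interval 3.16 to 6.46), U90926 (4.31), Nts (4.28), Ctla2a (3.72), the acute-phase genes Saa2 (3.57) and Serpina3m (3.56) and the IL-1 receptor antagonist Il1rn (3.35). On the low side were Cytl1 (-4.46, interval -5.61 to -3.51), Gzmd (-3.83), Defb6 (-3.48), Crabp1 (-3.29), Gzme (-3.21), Rsad2 (-3.14), Actg2 (-2.96), Npy (-2.53), Adamts16 (-2.51) and Hist1h3c (-2.43). With TMM factors the numbers above and below 0 were 26 and 1 for the inflammatory mediators, 9 and 0 for complement, 7 and 0 for the IL-4 and IL-13 genes, 11 and 0 for the cytokine receptors and 11 and 7 for the interferon genes. They were 0 and 21 for the cell cycle genes, 0 and 9 for the cycling markers, 5 and 9 for the myofibroblast, 3 and 8 for the lining, 0 and 4 for the tenocyte, 4 and 4 for the CD200/DKK3, 6 and 5 for the universal and 5 and 5 for the Wnt genes.

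Markers of other cells beside these were Tmem176a (1.64) and Tmem176b (1.44) of the ILC3 list, the monocyte gene Cd14 (1.62), the neutrophil gene Camp (1.39), the bone gene Ibsp (2.02), the cartilage genes Comp (0.34), Sox9 (-0.13) and Acan (-0.95), and Acta2 (-1.36) and Rgs5 (-0.94) of smooth muscle and pericytes. Further marker ratios were Mbp (1.40), S100b (-0.38) and Ncam1 (-0.01) of Schwann cells, Gzmb (0.71), Il1rl1 (-0.22), Areg (0.29) and Arg1 (-1.28) of lymphoid cells, Trdc (-0.55), Trbc2 (0.96) and Trac (-0.53) of T cells, and Ighm (-3.13, 2 against 17 UMIs; counting interval -6.29 to -1.05), H2-Aa (1.21) and Zbtb46 (-0.54). Eng (0.08), Egfl7 (-0.06), Emcn (0.48), Pecam1 (0.12), Lyz2 (0.47), Mrc1 (-0.04), Cd68 (-1.11), S100a8 (0.12), S100a9 (0.33), Retnlg (0.54), Des (0.19), Acta1 (0.10), Tnnt3 (0.29) and Mylpf (0.19) had intervals that include 0, as did Trbc2, Trac, Areg, Ncam1 and Zbtb46, and Abcc9 was at 0.62. Of these markers Mbp, Arg1, Trbc2, Trac, Ighm, H2-Aa, Emcn, Pecam1, Mrc1, Cd68 and Retnlg had fewer than 50 UMIs in both hashtags. The Il23mc hashtag held 66.5% Mmp3+, 23.8% Il6+, 5.77% Pi16+, 1.78% lining and 2.10% Cd200+ cells, against 69.5, 14.5, 8.48, 5.73 and 1.80% in the STA hashtag of the same well.

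**Figure D3:**
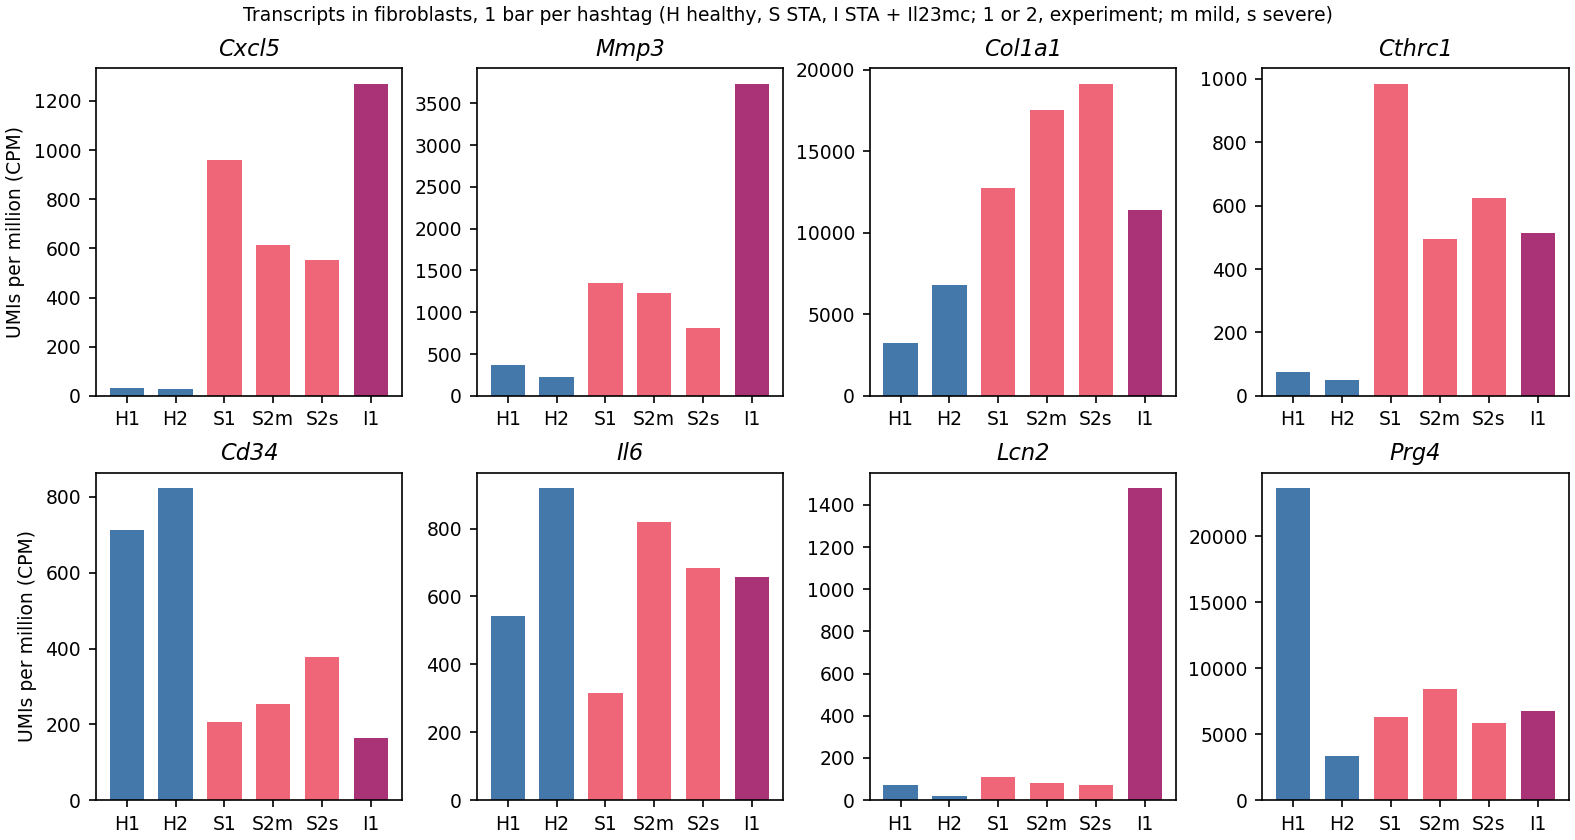
Level of 8 genes in fibroblasts (CPM on the y axis, 1 panel per gene) for the healthy, STA and STA + Il23mc hashtags, with 1 bar per hashtag named by condition and experiment. Cxcl5 lies at 28.0 and 30.7 CPM in the healthy hashtags and 554 to 961 CPM in the STA hashtags, and Mmp3 at 3732 CPM in the Il23mc hashtag.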

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

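Tests chosen after the result was seen are those of free RNA, of the doublet share and of Cd3g and Trdc for the Cd3 pattern, and the splits of the mice; the other tests were set before.

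In fibroblasts every STA hashtag of experiment 2 moved against that of experiment 1, with every counting interval excluding 0, for 3 of the named genes, a difference that was not tested. The log2 ratio of STA to healthy was -1.35 in experiment 1 against 1.75 and 1.14 in experiment 2 for Hbegf, and 2.85 against -1.55 and -2.06 for Trdc.

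Prg4, a lining gene, was at -1.91 in experiment 1 against 1.32 and 0.78 in experiment 2. Wrong hashtag calls are argued against, since in cells whose called tag also leads the ratios were -2.66 against 1.74 and 1.22. In sublining cells alone they were 2.06 against 1.70 and 1.13, so a different share of lining cells per hashtag may account for the sign. The sublining sums include the Mmp3+ class. A cluster of 489 cells, with Mmp3+ as its main class, was led by F13a1, Prg4 and Col22a1, which also led the lining cluster. Lining cells were 12.01% of the healthy hashtag of experiment 1 and 2.24% of that of experiment 2, or 22.8% (43 of 189 cells) and 1.78% in cells whose called tag leads. What set that share stays open, and no biological explanation was tested.

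Sorted cells outside the authors' annotation, which the comparisons here leave out except under 1 rule for calls and classes in all 3 wells, held Il17a at 1656 and 2137 CPM in Il23mc mice 1 and 2, above the healthy mice (0 to 83.5 CPM), and Cd3e at 526 and 469 CPM (healthy 0 to 280 CPM). Il23mc mouse 3, at 32.4 and 158 CPM, lay within the healthy range for both.

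Cells annotated ILC3 carried Cd3d or Cd3e UMIs in 410 of 462, 180 of 221 and 7 of 28 cells of Il23mc mice 1, 2 and 3, against 0 of 85, 2 of 150 and 33 of 463 in healthy mice. In mice 1 and 2 the share was at least 10.4 times that in ILC2-3 cells of the same mouse, a class picked after the result was seen. This argues against free RNA in mice 1 and 2, while free RNA stays open in mouse 3 (3.5 times). Over all ILC2 cells the contrast was smaller. There 128 of 191 cells in mouse 1 and 259 of 296 in mouse 2 held neither transcript, against 52 of 462 and 41 of 221 ILC3 cells. Doublets of an ILC3 and a T cell are argued against only by the share, with a lower bound of 75.7% where cross-tag doublets were 5.63% of the well, while the UMI ratio set before, 1.49, lay between its bounds of 1.3 and 1.6. T cells that passed the sort may be the source, as Cd3g and Trdc were at least 8.04 times the ILC3 cells of the highest healthy mouse (Cd3g at 1394 and 1517 CPM, Trdc at 703 and 644 CPM), but the test set before, the share with a receptor constant-gene UMI, is void (1.08 times, near 100% with and without). The labels give no gate for the sort, and no biological explanation, such as ILC3 cells that carry these transcripts, was tested.

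MHC class II transcripts rose in the ILC2 cells of STA mice, which filled a well of their own in experiment 1 and were classed by transfer, where 34.1 to 82.0% of the cells the authors left out were recognised. Free RNA stays open: in experiment 2, with 1 pool of free RNA, the median log2 ratio was 2.42 in the mild and 0.809 in the severe hashtag, the latter between the bounds of 0.5 and 1. Antigen-presenting cells or doublets stay open too, since 5% of the cells held 57.7% or more of the class II UMIs in each STA mouse (51.7 to 77.9% in healthy mice), while other markers of such cells were 0.459, 4.62 and 0.845 times as high there, from 3, 70 and 5 UMIs. The other 95% of cells held 120, 177 and 336 CPM in STA mice and 15.6 to 18.5 CPM in healthy mice. In the Il23mc mice, whose cells carry the authors' classes, the other 95% held 356, 315 and 163 CPM. There 5% of the cells held 53.7 to 62.7% of the class II UMIs. The other markers were 0.659, 1.82 and 0.966 times as high in them, from 1, 7 and 3 UMIs. Transfer of classes cannot account for the rise in the Il23mc mice, which also filled a well of their own. Expression in ILC2 cells themselves could not be told apart from free RNA, antigen-presenting cells or doublets.

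The 10 splits of 3 against 3 mice are too few for a share under 0.05. Of these, 1 reached the real count of 212 for STA against healthy (highest other 13), 1 reached 130 for Il23mc against STA (highest other 1), and 1 reached 553 for Il23mc against healthy (highest other 2). For any condition 1 of 100 splits reached the real 507 genes (highest other 132), which argues against a random grouping of the mice. In each of these tests the split that reached the count was the real one. The other splits mix mice of different conditions and wells, which raises the spread within their groups. Each condition was its own well, so the splits cannot tell condition from well.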

How the results depend on the processing

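Alternatives chosen after the data were seen are 1 rule for calls and classes in all 3 wells, the sums without cells holding Cd3d or Cd3e or without the ILC2-1 class, the term for sex, the cells whose called tag leads, and the Mmp3+, Il6+ and Pi16+ classes alone. Named genes that kept their call under every setting were 9 of 39 (STA against healthy in ILC2), 9 of 37 (Il23mc against STA), 33 of 60 (Il23mc against healthy) and 6 of 98 (fibroblasts). Among genes not called, 32, 34, 13 and 33 values, each of 1 gene in 1 setting, changed direction. Over all named genes and settings, in the same order, 150, 128, 104 and 393 values lost their call and 12, 10, 17 and 20 gained one. A further 1030, 932, 1210 and 1365 kept their call or stayed uncalled, and these include the uncalled values that changed direction. In Il23mc against STA fibroblasts 17 values moved beyond their counting interval and 15 did not.

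Counts of called genes in these comparisons (212, 130, 553 and 2481) ran, with DESeq2, upper-quartile factors and equal cell numbers, from 146 to 194, 110 to 121, 440 to 545 and 1786 to 2559. Without a filter more genes are tested, and 520, 394 and 863 ILC2 genes were called, with 1039 for any condition. The sum over all lymphoid cells gave 28 for STA against healthy; the cause was not tested. Leaving out 1 replicate, which leaves fewer samples, gave 58 to 302, 62 to 139, 327 to 587, 291 to 581 (any condition) and 841 to 2113 genes (fibroblasts). Without a healthy fibroblast hashtag 1 is left, assumed to vary like the other group. With the experiment term, the fits without the healthy or the STA hashtag of experiment 1 both rest on experiment 2 alone. In fibroblasts the count was 583 with no replicate block (no experiment term), 6 in lining, 512 in Mmp3+, 199 in Il6+ and 68 in Pi16+ cells, sets with fewer cells. Lists called went from 9, 5, 8 and 16 to 3, 2, 4 and 0 with an estimated correlation, where 2 fibroblast lists had an unadjusted camera p under 0.05, and to 15, 14 and 13 in ILC2 without a filter.

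The mouse numbers do not pair the mice: 3 of 9 correlate best with their own number, with same-number correlations from -0.132 to 0.143. With the number as a replicate block 206, 130, 523 and 483 (any condition) genes were called. With a term for sex, which is not balanced between the groups, they were 163, 148, 631 and 546; Fcer1g, Ldha, Zfp36, Dgat1, Rgs2, Cxcr6 and Itga4 lost their call for STA against healthy, and Il5 was called (0.95).

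The Pi16+ share difference was -21.999 points with rebuilt clusters (exact permutation p = 0.2) against -31.5, that of the Il6+ share -26.3 points (p = 0.1) against -8.89 (p = 0.3), and that of the ILC2 share, STA minus healthy, 18.7 points (p = 0.4) against 6.39. The rebuilt ILC2 share counts in a cluster, of 819 cells over all ILC wells, led by the mast cell genes Mcpt4, Cma1, Tpsb2 and Cpa3. The authors kept 411 of the 819 cells, and ILC2 was the main class of the cluster, so the main ILC2 sums hold such cells too. Areg was also among the leading genes of that cluster. The lining share difference was -7.45 points (exact permutation p = 0.6) in cells whose called tag leads, 189 of the 408 cells in the healthy hashtag of experiment 1, against -2.34 (p = 0.8). Share differences over the leave-outs ran from -5.11 to 13.2 points (ILC2, STA minus healthy) and -14.9 to 15.6 (ILC3, Il23mc minus healthy). Without Il23mc mouse 3, Il23mc minus STA was -19.5 points for ILC2 and 21.9 for ILC3 cells (exact permutation p = 0.1, the smallest that 2 against 3 mice can give), against -7.47 and 6.43. The Mmp3 log2 ratio of Il23mc to STA, 1.46, was 1.72 against the mean of 3 STA hashtags, 1.69 with TMM factors, 0.26 in lining, 1.42 in sublining and 1.52 in Mmp3+ cells; the cause was not tested.

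Direction changes follow, and the cause was not tested. Il23mc against STA in fibroblasts: against the mean of 3 STA hashtags Prg4 -0.015, Cd200 -0.43 and Pdgfra -0.034, and in lining cells Cd200 -0.046 and Pdgfra -0.18. In ILC2 cells without Cd3d or Cd3e, Thy1 was at -0.76 (Il23mc against STA) and Cd3g at -0.065 (against healthy), the latter a gene of the cells left out; with 1 rule for calls Top2a was at 1.00 (against healthy). In STA against healthy fibroblasts Prg4 was at 1.73 in sublining cells, and over the leave-outs Hbegf ran from -1.35 (without the experiment 2 healthy hashtag) to 1.48 and Trdc from -1.80 to 2.84 (without the same hashtag). Lining cells alone gave Chl1 -0.40, Ldha -0.012, Cox6c -0.34, Cox7c -0.084, Cd34 0.018, Sfrp1 -1.90, Postn -0.44, Cfb -1.10, Ptgs2 -1.56, Vcam1 -0.81, Ctsk -0.50, Pdgfra 0.18 and Ly6a 0.097. Mmp3+ cells alone gave Hmgb2 -0.16, Stmn1 -0.67, Mki67 -0.69, Gbp2 1.11, Ccnb2 -0.012, Cenpf -0.082, Acta2 -0.10, Abcc9 0.68, Fmod -0.095, Tnmd -0.14, Ccl11 1.13, Serping1 0.51, C4b 0.41 and Ctsl 0.56. Il6+ cells alone gave Gapdh -0.0202, Ldha -0.19, Ncam1 -0.32, Sox9 -0.12, Abcc9 0.25, Fmod -0.19, Ccl11 0.72, Sfrp4 1.11, Dkk2 0.63, Pdgfra 0.23, Ifngr1 0.22, Ly6a 0.085 and Dkk3 -0.63. Pi16+ cells alone gave Pkm -0.039, Junb 0.028, Gbp2 0.058, Cox7c -0.15, Ndufa4 -0.027, Sox9 -0.10, Acan -0.0503, Abcc9 0.083, Tnnt3 0.029, Fmod -0.27, Sfrp2 -0.0086, Dkk2 0.079, C4b 0.57, Ifngr1 0.14 and Ly6a 0.13.

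The stricter hashtag call, with the leading tag at least 10 times the next, was not run, since only 22 to 611 cells per well reach it. Depth limits the ILC2 tests: Il23r and Ifng did not pass the filter on low counts.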
